A study of Homo sapiens with 4 samples.

How the data were processed

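Gene expression had been measured with Affymetrix arrays in 4 samples of 2 human breast cancer cell lines, 1 array per group. Per the labels' protocols, stably transduced cells selected with puromycin were used, total RNA was extracted with a column kit, and biotinylated cRNA was made from 6 µg of it. The growth conditions in the labels were 37 °C for both lines, with 5% CO2 for MCF7 and 0% CO2 for MB231, so the carbon dioxide setting differed along with the cell line. The groups were taken from each sample's treatment label. The design text of the series names other cells, lung adenocarcinoma lines, and another gene, AK4, and so conflicts with the series title and with every sample label. The labels were followed, and AK4 was reported beside CCL2 in every array for that reason.

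The deposited values were probe set intensities on a linear scale, already normalized between arrays by the authors. The tool MAS5 is named per the submitters' processing notes, without a version or a role. The quantiles of the 4 arrays were nearly equal, and which summary and which scaling gave that was not given in the sources used here. The deposited values ranged from 4.30 to 29789.6 in arbitrary units over 54675 probe sets, 62 of them Affymetrix controls. They were not centred, and no further normalization was applied. Array medians were 48.3, 48.3, 48.9 and 48.5 for MCF7 control vector, MCF7 CCL2 overexpression, MB231 non-silencing shRNA and MB231 CCL2 shRNA, with the control probe sets left out.

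Probe sets were named from a table of the platform's annotation. It listed 42898 probe sets, of which 41097 had 1 gene symbol and 1801 had several. The other 11777 probe sets are unnamed here. Only probe sets with 1 symbol entered the gene table. Their gene identifiers were looked up in a table of RefSeq genes of assembly GRCh38.p14, used for names only. Of the identifiers, 41043 matched and 0 symbols had to be updated, which left 19775 genes. The probe set with the highest mean log2 signal over the 4 arrays stood for its gene.

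The median of each array served as its floor. A signal below the floor was raised to it before log2 was taken. A gene was called higher or lower where both arrays were above the floor and differed by at least 2-fold. Where no probe set of a gene was above the floor in 1 of the arrays, the ratio was taken as a bound and printed as "at least". Where the leading probe set was at the floor in 1 array and another probe set of the gene was above it there, the gene was neither called nor given a bound, but entered the list medians with the floor in place. This held for 25 genes in MCF7, 28 in MB231 and 83 between the control arrays. Genes at the floor in both arrays were given no ratio. There were no replicates, so no test was made and no p-value was computed. The size of measurement error was described in 2 ways. The first was the SD of log2 ratios over the probe sets of a gene above the floor in both arrays, pooled over genes and called the technical SD below. The second was the spread of the 18 hybridisation control probe sets, whose RNAs are added to every hybridisation. Neither contains the spread between cultures. The first is not measurement error alone, since it was 0.50 between the control arrays, against 0.16 in MCF7 and 0.14 in MB231. The SD of the hybridisation controls was 0.08 between the control arrays.

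The comparisons were CCL2 overexpression over control vector in MCF7, CCL2 shRNA over non-silencing shRNA in MB231, and the MB231 non-silencing array over the MCF7 control vector array. Gene names in the text followed a rule fixed before the data were examined. It took CCL2 and AK4 always. For each pair it took the 8 largest differences each way among genes past 2-fold whose other probe sets above the floor went the same way, the 4 largest bounds each way past 2-fold, and up to 2 members each way of each gene list past 2-fold. For genes shared between the pairs it took the 6 genes per pattern with the largest smaller difference. For the control arrays it took list members and the 4 largest differences and bounds each way. Only 8 genes were past 2-fold over both pairs, so the rule was also applied at 1.5-fold, and genes with all of at least 2 probe sets past 1.5-fold were listed. Both additions were chosen after seeing the data, as were the genes named outside these rules.

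The 24 gene lists, with 428 different genes, were also fixed before the data were examined, and 397 of those genes were named on the array. A list's measured genes were those above the floor in at least 1 of the arrays compared. The median log2 ratio of a list was set among those of 10000 random lists of the same size, drawn from 20 bins of mean expression, and its percentile describes these arrays only. Lists with under 3 measured genes were given no percentile. Counts of list members past 2-fold include bounds. The lists share some genes. Shuffles of gene ratios within bins of mean expression, 10000 in number, described the overlap between the pairs, and 1000 shuffles of gene labels the correlation between the 2 probe sets of a gene that came earliest by name.

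The procedure was tested on simulated data made from the real signals of 19775 genes. Of 100 genes given a log2 change of 1.5, 93 were called the right way in the simulated MCF7 pair and 87 in the simulated MB231 pair. Of 100 genes given a change of 0.4, 0 were called in either, and 0 unchanged genes were called. The second array of each simulated pair was the control array with independent normal noise of a fixed SD, small against the 2-fold threshold. Both counts of 0 were thus all but fixed in advance and do not measure false calls in the real pairs. A list of 20 genes shifted by 0.2 was at percentile 100 in both, against 52.5 and 73.4 without the shift. That shift was larger than every list median within the real pairs, and the noise was independent between probe sets. The result therefore does not measure how smaller shifts, or lists whose genes vary together, would rank.

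Each count, list median and named gene was recomputed with the floor at the 25th and at the 65th percentile, with the median signal as a pseudocount in place of the floor, with a median shift, with quantile normalization, with a loess correction of span 0.4 within each pair, with the median over probe sets of a gene, and with specific probe sets only, meaning those without _s_, _x_ or _a_ in their name. Counts were also taken at 1.5-fold and 3-fold. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. No scanner files or genome were used here.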

Results

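Genome-wide expression was measured on 4 Affymetrix arrays, 1 for each of 4 stably transduced populations of human breast cancer cells. MCF7, an estrogen receptor positive line with an epithelial phenotype, carried either a control vector or a CCL2 expression vector. MB231, a line that lacks the estrogen receptor and has a mesenchymal phenotype, carried either a non-silencing shRNA or an shRNA against CCL2. CCL2 encodes a chemokine that attracts monocytes through the receptor CCR2. The labels pose the question of what CCL2 gain does to expression in MCF7 and what CCL2 loss does in MB231. Each array gave signals for 54675 probe sets, and the median of an array, between 48.3 and 48.9, served as its floor. There were no replicates, so every ratio below compares single arrays and the number of arrays limits its precision. Across probe sets, the log2 signals correlated at r = 0.996 between the MCF7 arrays, at 0.997 between the MB231 arrays and at 0.911 to 0.913 between the lines. Probe sets are not independent replicates.

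CCL2, the targeted gene, was below the floor in all 4 arrays. Its 1 named probe set, 216598_s_at, read 10.5 in the MCF7 control vector array and 11.1 in the array labelled CCL2 overexpression. It read 11.4 in the MB231 non-silencing array and 10.1 in the array labelled CCL2 shRNA. These signals were at percentiles 13.3, 14.6, 14.8 and 11.99 of their arrays. The 27 probe sets for bacterial transcripts other than the hybridisation controls had medians of 9.55, 10.1, 9.37 and 10.3 in the same order. Their single values ran from 5.90 to 49.6, so that CCL2 lay within their range. They were picked by name, and that their transcripts were not added to the samples was assumed. No CCL2 ratio was therefore taken, the arrays bore out neither the overexpression nor the knockdown, and every direction given below rests on the labels. Including CCL2, 8 of the 9 named genes of the CCL2 axis were at the floor in both arrays of each pair, its receptor gene CCR2 among them. The remaining member, CCR4, had log2 ratios of -0.08 in MCF7 and -0.08 in MB231.

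AK4, the gene named in the design text, is an adenylate kinase of the mitochondrial matrix. Its 4 probe sets were all above the floor in all 4 arrays. Their log2 ratios were -0.14, -0.21, -0.05 and 0.09 in the MCF7 pair and 0.02, 0.18, 0.25 and 0.24 in the MB231 pair. The markers of the cell lines went with the labels. The estrogen receptor gene ESR1 read 3198 and 3328 at probe set 205225_at in the MCF7 arrays, against 14.0 and 14.6 in the MB231 arrays. GATA3, a luminal transcription factor, read 16840.2 and 17324 against 510 and 488, and vimentin, VIM, a mesenchymal filament protein, read 64.3 and 60.2 against 13878 and 13951. Of the lung lineage genes, NKX2-1 did not exceed 54.1 in any array, while SFTPB, a surfactant protein gene, was near or below the floor at 2 of its 4 probe sets and above it in all 4 arrays at the others, with 125, 109, 117 and 98.1 at 213936_x_at.

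**Figure D1:**
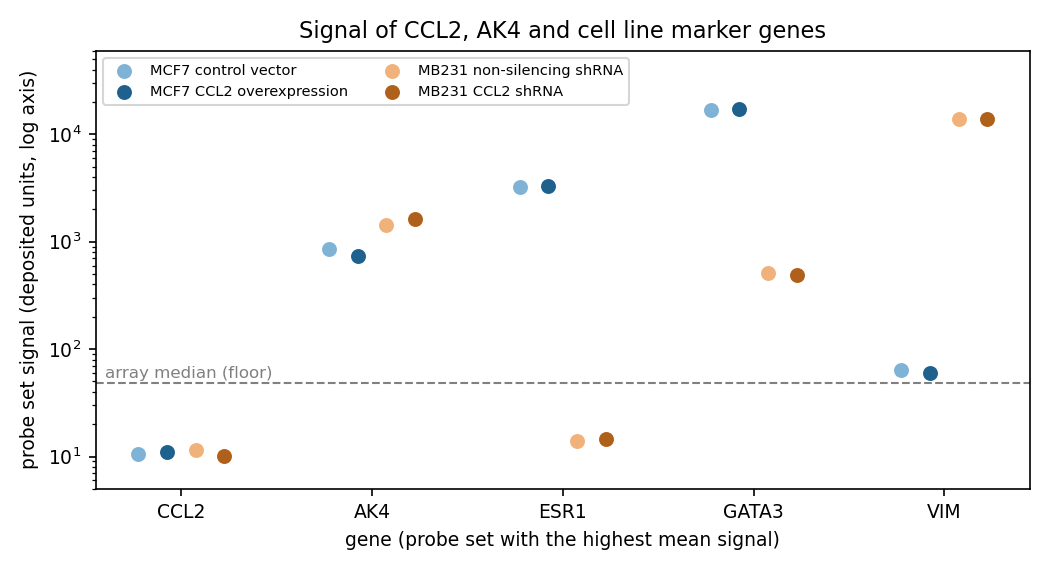
Signal of 5 genes (deposited units, log axis) at the probe set of each with the highest mean signal, with a point for each of the 4 arrays and a dashed line at the array median. CCL2 lies below the line in all 4 arrays, between 10.1 and 11.4, while ESR1 and GATA3 are higher in MCF7, VIM is higher in MB231 and AK4 is above the line in every array.

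In the MCF7 pair, a gene for a regulator of G protein signalling, RGS22, and the calmodulin-like gene CALML5 were higher in the array labelled CCL2 overexpression, and the open reading frame C8orf88 was lower. RGS22 read 107 against 51.7, a 2.07-fold difference, and CALML5 887 against 443, a 2.004-fold difference. C8orf88 read 119 against 287, a log2 ratio of -1.27 with an SD of 0.51 over 2 probe sets. These were the 3 genes past 2-fold among 12407 above the floor in both arrays, or 0.0242%. The SD of the log2 ratios over all these genes was 0.19, and the technical SD was 0.16 over 5912 genes with several probe sets. The 18 hybridisation controls had a median log2 ratio of 0.06 with an SD of 0.06. Another 546 genes were above the floor in 1 of the arrays, and 0 of them had a bound past 2-fold. With a pseudocount in place of the floor, 0 genes were past 2-fold in this pair, and CALML5 stood at the threshold, since its log2 ratio was 1.003.

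At 1.5-fold, 69 genes were higher and 39 lower in the array labelled CCL2 overexpression, with a further 8 and 1 as bounds. The higher genes included the homeobox genes HOXC13, with a log2 ratio of 0.96, and HOXB2, with 0.86. CAPN9, a calpain protease, had a ratio of 0.93 with an SD of 0.05 over 2 probe sets, and CGNL1, a component of epithelial junctions, had 0.90. EPB41L4A had 0.91 and the antisense transcript GPC1-AS1 0.93. The lower genes included NPY1R, a receptor for neuropeptide Y, at -0.97, and TFPI, an inhibitor of the tissue factor pathway of coagulation, at -0.96 with an SD of 0.06 over 3 probe sets. NECAB1 was at -0.96, LINGO1 at -0.88, the noncoding transcript LINC00052 at -0.88, the zinc finger factor EGR3 at -0.85, and NT5E, an enzyme that makes extracellular adenosine, at -0.85 with an SD of 0.18 over 2 probe sets. Among genes at the floor in the control array, DAPK1, CDC42EP5, the histone gene H2AC15 and CFAP263 were at least 1.74-fold, 1.65-fold, 1.62-fold and 1.61-fold higher, and H2AC15 is uncertain because histone genes are near-identical copies. The collagen chain gene COL4A5 was at least 1.75-fold lower.

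In 9 genes with several probe sets above the floor, each probe set was past 1.5-fold the same way in MCF7. The 5 lower ones were FAM133A, with a mean log2 ratio of -1.05 ± 0.44 (SD over 2 probe sets), TFPI with -1.02 ± 0.06 over 3, NT5E with -0.72 ± 0.18 over 2, KYNU, an enzyme of tryptophan breakdown, with -0.68 ± 0.04 over 3, and the collagen gene COL12A1 with -0.66 ± 0.06 over 2. The 4 higher ones were CAPN9 with 0.90 ± 0.05, the GTPase gene RAB39B with 0.73 ± 0.10, the cell adhesion gene CEACAM6 with 0.69 ± 0.06 and the kinase gene RPS6KA2 with 0.64 ± 0.04, each over 2. Across the 5912 genes with several probe sets, the log2 ratios of a gene's 2 probe sets that came earliest by name correlated at r = 0.34, against at most 0.04 after shuffling. Genes are not independent replicates. Of 42 genes past 1.5-fold with several probe sets above the floor, the probe set next in mean signal went the same way in 34, or 81.0%, and was past 1.5-fold in 9.

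No gene list had a member past 2-fold in MCF7, and the list medians farthest from 0 were 0.13 and -0.13 on the log2 scale. The immediate early genes, transcription factors and regulators that respond within minutes to stimulation, had a median of -0.12 in the array labelled CCL2 overexpression over its control, with 14 of 16 measured genes below 0 but only 1, EGR3, past 1.5-fold. EGR3 was at -0.85, FOSB at -0.56, CCN2 at -0.51 and FOS at -0.32. This median was at percentile 0.17 among random lists of the same size, and at 3.29 with specific probe sets only, inside the central 95% of random lists. The p53 targets had a median of 0.13 with 12 of 15 genes above 0. They were led by the cell cycle inhibitor gene CDKN1A with 0.63, TP53INP1 with 0.46 and FAS with 0.44. TP53INP1 had an SD of 0.37 over 2 probe sets. The median of the p53 targets was at percentile 99.7. With specific probe sets only, that median was 0.0051 at percentile 57.3. The epithelial genes had a median of 0.09 with 16 of 21 above 0, at percentile 99.6. Among them were the protease gene ST14 with 0.35, with an SD of 0.36 over 2 probe sets, and RAB25 with 0.27. The unfolded protein and ATF4 response had a median of 0.08 with 16 of 19 above 0, at percentile 98.6, with PHGDH at 0.47 and CHAC1 at 0.34, and at percentile 96.8 with the median over probe sets. The estrogen response genes had a median of 0.07 with 16 of 24 above 0, at percentile 97.8, but went both ways, with SERPINA1 at 0.49 and STC2 at 0.38 against PDZK1 at -0.47 and GREB1 at -0.33, and the list was at percentile 94.1 with the floor at the 65th percentile. The label check genes, a mixed list of markers, had a median of -0.13 at percentile 1.96, and of 0.0047 at percentile 57.6 with specific probe sets only. Of 8 alternative settings, the median stayed outside the central range in 8 for epithelial genes, in 7 each for immediate early genes, p53 targets and the unfolded protein and ATF4 response, in 4 for label check genes and in 3 for estrogen response genes.

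The other 17 lists with a median in MCF7 were inside the central 95% of random lists. Antigen presentation had the largest of these medians, 0.13 at percentile 97.4, followed by interferon-stimulated genes with 0.11. TGF-beta targets had 0.08, NF-kB targets 0.07, other chemokines and cytokines 0.06, glycolysis 0.04, stem cell and Notch genes 0.04 and apoptosis regulators 0.03. Cholesterol synthesis had -0.08, mesenchymal genes -0.06, proliferation genes -0.05, proteases and invasion genes -0.05, oxidative phosphorylation -0.04 and hypoxia genes -0.03. Markers of other cell types were mostly at the floor, with 4 of 14 leukocyte markers, 6 of 12 fibroblast markers and 3 of 10 endothelial markers measured and medians of 0.07, -0.0063 and 0.06. With specific probe sets only, TGF-beta targets turned to -0.14 at percentile 0.81, antigen presentation to -0.03 and mesenchymal genes to 0.13, while proliferation genes were at percentile 0.76 and proteases and invasion genes at 2.065. With the median over probe sets, TGF-beta targets were at percentile 99.5 and cholesterol synthesis and hypoxia genes turned to 0.04 and 0.0059. Antigen presentation was at percentile 98.7 with a pseudocount and 97.7 with quantile normalization, and the endothelial median turned to -0.03 with the floor at the 25th percentile.

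In the MB231 pair, MCTP1, a membrane protein that binds calcium, and the antisense transcript TBX2-AS1 were higher in the array labelled CCL2 shRNA, and SPANXB1, the homeobox gene MNX1 and the water channel gene AQP3 were lower. MCTP1 read 390 against 180, a log2 ratio of 1.12 with an SD of 0.52 over 3 probe sets, and 0.27 as the median over its probe sets. TBX2-AS1 had a ratio of 1.08 and MNX1 -1.02. SPANXB1 had -1.17 and is uncertain, since near-identical copies of the gene can share its probe set. AQP3 had -1.07, but its 3 probe sets did not all go the same way and their SD was 0.75, so it falls outside the naming rule and was named after its value was seen. These were the 5 genes past 2-fold among 12550 above the floor in both arrays, or 0.0398%. The SD of all log2 ratios was 0.15, the technical SD 0.14 and the median of the hybridisation controls -0.06. Another 443 genes were above the floor in 1 of the arrays, and 0 of them had a bound past 2-fold. With a pseudocount in place of the floor, 0 genes were past 2-fold in this pair.

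At 1.5-fold, 19 genes were higher and 15 lower in the array labelled CCL2 shRNA, with a further 1 and 4 as bounds. The higher genes included the forkhead factor FOXQ1, with 1155 against 650 and a log2 ratio of 0.83, the desmosomal gene PPL with 0.80, the decoy receptor gene TNFRSF10D with 0.75 and the mitochondrial carrier gene UCP3 with 0.71. SCAND2P had 0.78 and TFAP2A-AS1 0.69. The lower genes included DAW1 at -0.98, LOC100190986 at -0.93, the growth factor gene PTN at -0.70 with an SD of 0.25 over 3 probe sets, USP46-DT at -0.63 and the protease inhibitor gene SERPINI1 at -0.63. GTF2H2B was at -0.79 and is uncertain because of near-identical copies. RBP7 was at least 1.57-fold higher. ADAMTS6, the surface glycoprotein gene CD24, the adrenergic receptor gene ADRA2C and CYP2J2 were at least 1.87-fold, 1.65-fold, 1.61-fold and 1.53-fold lower. In MB231, 0 genes had several probe sets that were all past 1.5-fold the same way. The correlation between 2 probe sets of a gene was r = 0.23 across 5950 genes, against at most 0.03 after shuffling. Of 7 genes past 1.5-fold with several probe sets above the floor, the next probe set went the same way in 5 and was past 1.5-fold in 0, with a median of 0.16 in the direction of the leading one.

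No gene list had a member past 2-fold in MB231 either, but 6 list medians were above and 1 below the central 95% of random lists. Cholesterol synthesis had a median of 0.13 with 12 of 14 genes above 0, among them LSS with 0.27 and FDPS with 0.21, at percentile 99.9. Hypoxia genes had a median of 0.12 with 13 of 18 above 0, among them NDRG1 with 0.44, MXI1 with 0.34 and BNIP3L with 0.33, at percentile 100. Glycolysis had 0.06 with 16 of 19 above 0, among them ENO2 with 0.28 and the glucose transporter gene SLC2A1 with 0.25, at percentile 98.0. Mesenchymal genes had 0.11 with 11 of 14 above 0, with the transcription factor gene ZEB1 at 0.44 and SNAI1 at -0.33, at percentile 99.9. Other chemokines and cytokines had 0.12 with 9 of 14 above 0, at percentile 99.7. CCL28 was at 0.50, with an SD of 0.39 over 2 probe sets, and CXCL1 at 0.40, against IL11 at -0.51. Antigen presentation had 0.08 with 10 of 15 above 0, at percentile 98.6. Proteases and invasion genes had -0.07 with 10 of 18 below 0 at percentile 0.74, with ADAM19 at -0.55 and PLAT at -0.39 against ITGB3 at 0.57. With specific probe sets only, the medians of mesenchymal genes, glycolysis and antigen presentation were at percentiles 91.4, 68.7 and 75.9, and that of proteases at 4.24, or at 9.54 with the floor at the 25th percentile. Cholesterol synthesis, hypoxia genes and other chemokines stayed outside the central range in 8 of 8 alternative settings, mesenchymal genes in 7, glycolysis and proteases in 5 and antigen presentation in 4.

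The other 16 lists with a median in MB231 were inside the range of random lists. p53 targets and epithelial genes had medians of 0.06 and 0.07. The unfolded protein and ATF4 response had 0.05, estrogen response genes 0.05, stem cell and Notch genes 0.05, oxidative phosphorylation 0.04, TGF-beta targets 0.03, apoptosis regulators 0.03, immediate early genes 0.02, label check genes 0.0076 and proliferation genes 0.0066. NF-kB targets had -0.0030 and interferon-stimulated genes -0.03. Of the markers of other cell types, 6 of 14 leukocyte, 6 of 12 fibroblast and 4 of 10 endothelial markers were measured, with medians of -0.04, 0.15 and 0.02. With specific probe sets only, interferon-stimulated genes were at -0.10 and percentile 0.80, p53 targets at 0.15 and percentile 99.4, and label check genes at 0.21 and percentile 99.35. With the median over probe sets, interferon-stimulated genes were at percentile 1.43 and fibroblast markers at 98.3, the latter also at 98.0 with the floor at the 25th percentile. The medians of estrogen response genes, label check genes, proliferation genes, oxidative phosphorylation, TGF-beta targets, NF-kB targets and leukocyte markers turned sign in at least 1 setting. Over both pairs, 13 of 46 list medians were outside the central 95%, where 2.3 would be if the lists were random and independent. Genes of a list may vary together between cultures, which the random lists do not carry. More than 2.3 can therefore fall outside without an effect of CCL2.

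**Figure D2:**
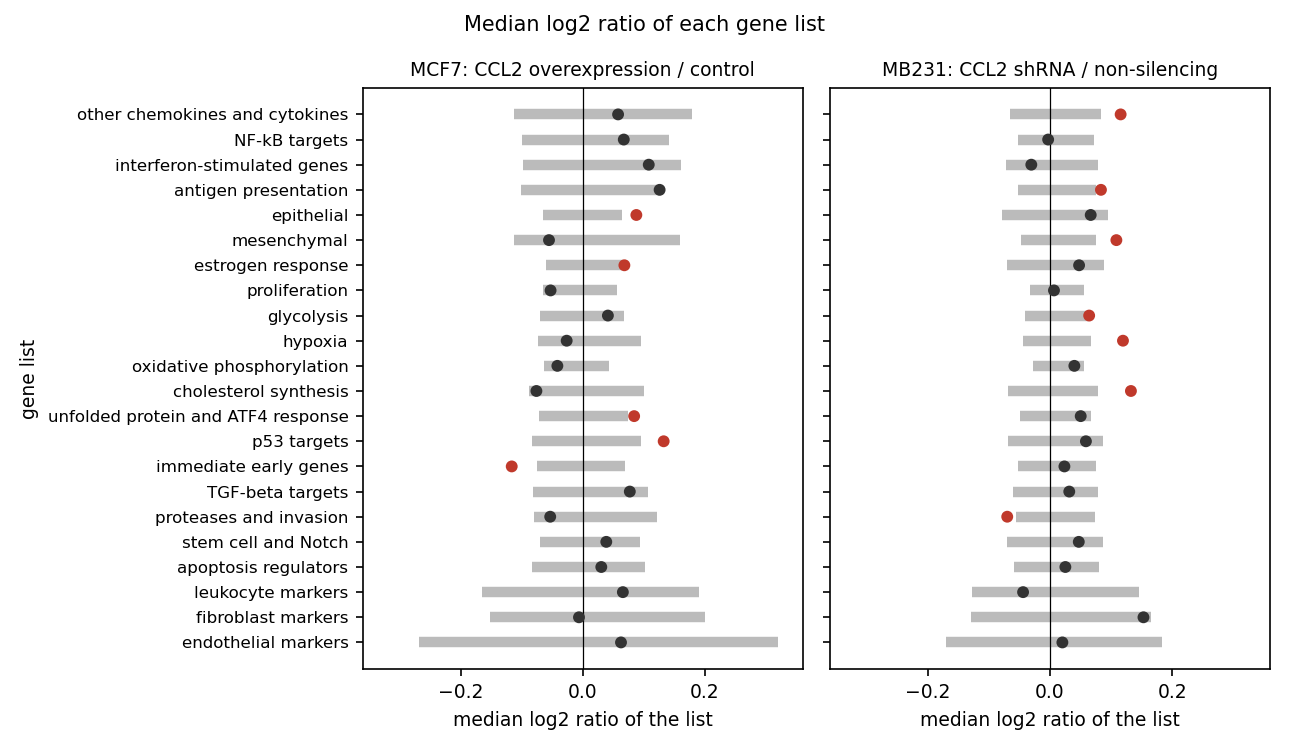
Median log2 ratio (x axis) of the gene lists with a median, except the label check genes, in MCF7 (left) and MB231 (right). A grey bar covers the central 95% of 10000 random lists matched on size and expression. The label check genes, outside that range in MCF7 at -0.13, are not shown. Red points lie outside that range, as do immediate early genes at -0.12 in MCF7 and hypoxia genes at 0.12 in MB231, and black points lie inside it.

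The design sets CCL2 gain in one line beside CCL2 loss in the other, so the pairs were compared for genes that went opposite ways. Of 11630 genes above the floor in all 4 arrays, 0 were past 2-fold in both pairs. At 1.5-fold, by the leading probe set of each gene, 0 went opposite ways, where 0.0534 would by chance. The same way went 1 gene, where 0.0577 would. That gene was NUPR1, a stress-induced regulator of transcription, with log2 ratios of 0.73 in MCF7 and 0.64 in MB231. Across the 11630 genes, the ratios of the pairs correlated at r = -0.054 and rho = -0.071, where shuffled ratios gave r from -0.021 to 0.017. Genes are not independent replicates here either. Ranked by the smaller of the 2 differences, the leading genes higher in MCF7 and lower in MB231 were GPRC5A (0.42 and -0.55), AKR1C1 (0.41 and -0.48), C1R (0.41 and -0.52), PARP10 (0.97 and -0.41), CYSRT1 (0.38 and -0.55) and SLC9A5 (0.40 and -0.38). Those lower in MCF7 and higher in MB231 were LINC00491 (-0.59 and 0.52), MID2 (-0.49 and 0.44), TMPRSS13 (-0.45 and 0.44), PTGES (-0.42 and 0.63), SMIM11 (-0.46 and 0.42) and LCP1 (-0.67 and 0.41). In PARP10, 3 of 4 probe sets went the way of the leading one in MCF7 and 1 of 4 in MB231. Other probe sets than the leading one can differ, as in MALAT1, picked after its values were seen. Its leading probe set, 224567_x_at, had -0.31 in MCF7 and 0.04 in MB231. Past 1.5-fold in opposite ways were 224559_at, with 1.51 and -0.93, and 228582_x_at, with 0.87 and -1.0001.

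**Figure D3:**
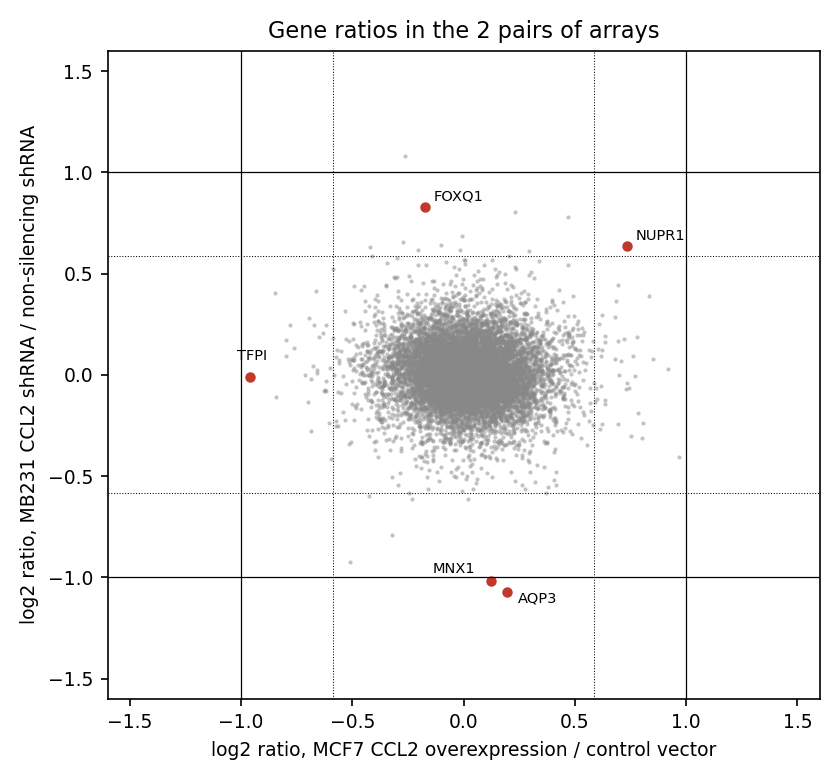
Log2 ratio in MB231 (y axis) against log2 ratio in MCF7 (x axis) for the 11630 genes above the floor in all 4 arrays, 1 point per gene, with solid lines at 2-fold and dotted lines at 1.5-fold. Each gene is plotted at its leading probe set, and there none lies past 1.5-fold in opposite directions in both pairs. NUPR1 lies past it the same way in both, and the other genes marked in red are past 1.5-fold in 1 pair.

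The control arrays differed on a scale far above that within the pairs. They differed in cell line, but also in vector and in the labelled carbon dioxide setting, and these cannot be told apart here. Of 11869 genes above the floor in both control arrays, 1339 were past 2-fold higher and 1427 lower in MB231, or 23.3%, with 403 and 340 further genes as bounds. The SD of the log2 ratios was 1.05. Among these genes, the highest in MB231 were VIM with 7.75, the urokinase gene PLAU with 6.96, LDHB with 6.86 and S100A4 with 6.64. Their lowest were CD24 with -7.25, FXYD3 with -6.56 and an SD of 2.87 over 2 probe sets, TSPAN13 with -6.53 and the estrogen-regulated gene GREB1 with -6.33. Among genes at the floor in MCF7, IL6, IL11, the tissue factor gene F3 and EDIL3 were at least 160-fold, 139-fold, 106-fold and 89.3-fold higher in MB231. Among genes at the floor in MB231, TFF1, DSCAM-AS1, AGR2 and the E-cadherin gene CDH1 were at least 443-fold, 342-fold, 269-fold and 232-fold lower. A further 83 genes had their leading probe set at the floor in 1 of the arrays and another probe set above it there, and were neither called nor given a bound. With the floor in place, 36 of their leading probe sets were past 2-fold higher and 32 lower, with 7.33 for AXL and -6.68 for SOX4 the farthest from 0.

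Epithelial genes had a median log2 ratio of -3.39 between the control arrays, with 20 of 21 measured genes past 2-fold lower in MB231, bounds included here as in the list counts below, the other being OVOL1, one of the 83 genes not called or bounded, with 46.7 against 313, and the splicing regulator gene ESRP1 at least 55.3-fold lower. Estrogen response genes had a median of -2.80, with 17 of 24 lower and 1, SERPINA1, higher, and ESR1 was not called for the same reason. Mesenchymal genes had a median of 4.20, with 11 of 14 higher, and AXL, at 7782 against 21.8, was not called. NF-kB targets had a median of 1.76 with 15 of 18 higher, and CXCL8 at least 79.2-fold. Other chemokines and cytokines had 1.75 with 8 of 16 higher and 2, CXCL16 and CXCL12, lower. Antigen presentation had 2.17 with 13 of 15 higher, among them the immunoproteasome genes PSMB8 and PSMB9, at least 25.6-fold and 19.7-fold. Interferon-stimulated genes had 1.54 with 9 of 19 higher, IFI27 at 3.70 among them, and IFIT3, at 2343 against 11.7, was not called. With the median over probe sets, interferon-stimulated genes were inside the central 95% of random lists at 0.20 and percentile 84.8, and other chemokines and cytokines at 0.42 and percentile 97.0. Proteases and invasion genes had 1.17 with 9 of 18 higher, led by PLAU and its receptor gene PLAUR with 4.47, and 1, ITGB4, lower at -2.30. Hypoxia genes had 0.96, with ADM at 4.65 and LOX at least 30.6-fold higher, and STC2 at least 41.6-fold lower. TGF-beta targets had 0.51 with 6 of 17 higher and 2 lower, TGFB2 with 3.14 and BMP4 with 2.34 against ID2 with -3.17 and LTBP3 with -1.89. LTBP3 had 3 probe sets with an SD of 1.101, and its ratio was 0.30 with specific probe sets only.

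Immediate early genes had a median of -1.34 between the control arrays, with 9 of 17 past 2-fold lower, EGR3 at least 32.9-fold and ATF3 with -3.24 among them, and 3 higher, FOSL1 at least 25.9-fold and CCN1 with 3.41 among them. p53 targets had -0.85 with 7 of 15 lower, GDF15 with -6.26 and TP53INP1 with -2.62, and 2 higher, TNFRSF10B with 1.98 and TP53I3 with 1.62. Cholesterol synthesis had -0.70 with 5 of 14 lower, SQLE with -3.01 and DHCR7 with -1.70, and 1, STARD4, higher with 2.19. The unfolded protein and ATF4 response had -0.64 with 8 of 20 lower, XBP1 with -4.18 and PHGDH with -3.61, and 2 higher, PPP1R15A with 2.63 and DDIT4 with 1.33, while PSAT1, at 3338 against 15.7, was not called. Stem cell and Notch genes had -0.68 with 6 of 16 lower, CD24 and DLL1, and 4 higher, ITGA6 with 4.47 and CD44 with 3.91. SOX2, at 9.88 against 1908, and SOX4, at 17.9 against 5003, were not called, and the list's median was 0.076 when a gene's value was the median over its probe sets. These 15 medians were outside the central 95% of random lists. With specific probe sets only, immediate early genes were inside it at -0.39 and percentile 8.57, the unfolded protein and ATF4 response at -0.30 and percentile 13.1, TGF-beta targets at percentile 94.8 and stem cell and Notch genes at 7.76. With the floor at the 65th percentile, TGF-beta targets were at percentile 95.9 and stem cell and Notch genes at 11.1, the latter also at 27.4 with the floor at the 25th. The other 8 lists were inside it, namely glycolysis with 0.35, proliferation genes with 0.24, leukocyte markers with 0.23, apoptosis regulators with 0.23, endothelial markers with 0.22, fibroblast markers with -0.01, oxidative phosphorylation with -0.05 and label check genes with -0.12. With specific probe sets only, proliferation genes, leukocyte markers and label check genes were outside it, at percentiles 98.2, 99.9 and 0.10, and apoptosis regulators, fibroblast markers and oxidative phosphorylation turned to -0.22, 0.69 and 0.04. Label check genes turned to 0.11 with the median over probe sets. Members of these lists past 2-fold included ENO2 with 2.42 and SLC2A3 at least 7.50-fold higher, the thymidylate synthase gene TYMS with 1.23 and BUB1 with 1.07, and SDHD with 1.11 against UQCRC2 with -1.07. BIRC2 had 2.61 and PMAIP1 1.53, against BIK with -2.70 and XIAP with -1.29. LAPTM5, COL6A3 and ESAM were at least 27.1-fold, 9.42-fold and 2.43-fold higher in MB231, COL3A1 was at least 22.3-fold lower and ACTA2 had -1.096. CCR4 was the 1 measured gene of the CCL2 axis, and GATA3 had a ratio of -5.05 with an SD of 0.60 over 3 probe sets.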

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

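The tests of AK4, of the CCL2 percentile, of the CCL2 probe set and of agreement between probe sets were chosen after the result was seen, and those of a level trend and of a common CCL2 effect before.

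CCL2 was near the median signal of the bacterial control probe sets assumed to be unoccupied in every array, including the array labelled CCL2 overexpression. A gain of AK4 RNA in MCF7 and a loss in MB231, for an AK4 experiment as in the design text, were not seen. The highest AK4 log2 ratio over 4 probe sets was 0.094 in the MCF7 pair, and the lowest was 0.020 in the MB231 pair. All 4 AK4 probe sets were above the floor in every array, so such changes could have shown at their targets. With 1 array per group, the ratios argue against an AK4 gain in MCF7 and an AK4 loss in MB231 of 1.5-fold or more. CCL2 was below the floor in every array, so no ratio was taken and a loss in MB231 could not have shown. Scaling between arrays that keeps the order within an array cannot have hidden a high CCL2 signal. CCL2 stood at percentile 14.6 of the array labelled CCL2 overexpression. Whether the authors' processing kept that order was not given in the sources used here. An expressed CCL2 transcript that lacks the target of the probe set stays possible for MCF7, since only 1 CCL2 probe set was named and it cannot separate parts of the transcript. That explanation may not extend to MB231, where endogenous CCL2 would carry the target, and a low CCL2 level in these cultures remains open and untested.

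The differences within the pairs were small. Noise independent between probe sets, as the whole cause of the differences over all genes, is argued against by the correlation between probe sets of the same gene. It was r = 0.34 in MCF7 and 0.23 in MB231. Overlap of the targets of such probe sets was not checked, and they read the same labelled RNA. Errors that they share could give such a correlation and are not excluded. Noise stays possible for the genes past 1.5-fold in MB231. Of the 7 with several probe sets above the floor, the next probe set went the same way in 5, or 71.4%, was past 1.5-fold in 0 and had a median of 0.16 in that direction. In MCF7 it went the same way in 34 of 42 and was past 1.5-fold in 9. A loess correction kept 95.4% and 97.1% of the genes past 1.5-fold, so a smooth trend with signal level does not account for most of these calls. Such large ratios are little moved by a small trend, so this does not exclude one in the small list medians. With loess, estrogen response genes in MCF7 came inside the central range at percentile 96.8, and glycolysis in MB231 at 97.465. The other lists outside it stayed outside. An effect of CCL2 common to both lines stays open, because r between the pairs was -0.054, below the shuffled range, whose low end was -0.021, but above the -0.1 set beforehand for such an effect. Differences between cultures, passages or transduced pools could give the same values and cannot be told apart from an effect of CCL2 with 1 array per group.

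NUPR1 was higher in both manipulated arrays, with log2 ratios of 0.73 and 0.64, although the labels give opposite manipulations of CCL2. The difference between the pairs was not tested. Among probe sets not listed in the annotation, 3 of 2816 above the floor were past 2-fold in MCF7 and 1 of 2720 in MB231. The 1801 probe sets with several gene symbols were in neither these counts nor the gene table.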

How the results depend on the processing

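All alternatives in this part were planned before the data were examined, except the lists of named genes at 1.5-fold, which were added after. The counts within the pairs are small numbers of genes and moved with most settings, and the causes were not tested. With the floor at the 25th percentile, 6 genes were higher and 4 lower in MCF7, and 4 and 8 in MB231. At the 65th percentile, 1 was higher in MCF7, and 1 was higher and 1 lower in MB231. With a pseudocount, all 4 counts were 0. With a median shift, as with quantile normalization, 1 gene was higher in MCF7. With the median over probe sets, 2 were lower in MCF7 and 1 was higher in MB231, and with specific probe sets only 2 were lower in MCF7. By construction, counts at 1.5-fold were larger, with 69 higher and 39 lower in MCF7, 19 and 15 in MB231, 2468 and 2531 between the control arrays, and 1 gene the same way in both pairs. At 3-fold they were 0 in each direction of both pairs, and 634 and 623 between the control arrays. CCL2 was above the floor in 0 arrays under each floor and each between-array scaling run. By the value that stood for each gene, 0 genes went opposite ways in the pairs under any setting. The thresholds of 1.5-fold and 3-fold were run with the leading probe sets only. Single probe sets of MALAT1, described below, did go opposite ways past 1.5-fold. The scalings moved the median of all genes by at most 0.02. Of 1.5-fold genes, a floor at the 65th percentile kept 67 of 108 in MCF7 and 16 of 34 in MB231, and a pseudocount 45 and 11, so low signals decide many calls. Counting as reversed a list outside the central range, or a named gene past its threshold, that changed sign, the reversed values were 0.076 for stem cell and Notch genes between the control arrays with the median over probe sets, and, with specific probe sets only, 0.30 for LTBP3 there and 0.0047 for label check genes in MCF7. Over settings, 476 list medians stayed within 1 SD of random lists, 66 moved further and 2 reversed, and 689 values of named genes stayed, 129 moved and 1 reversed. Of the 544 list medians recomputed, 26 changed sign, 24 of them of lists inside the central range, such as TGF-beta targets in MCF7 with -0.14 and apoptosis regulators between the control arrays with -0.22, both with specific probe sets only. In 33 cases a list outside the central range came inside it, and in 15 the opposite. No fit over both pairs was run. One of cell line and CCL2 label over the 4 arrays would have left 1 residual degree of freedom.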

Other observations

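The genes in the first 2 paragraphs, and both tests of MALAT1, were chosen after their values were seen.

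Other genes past 1.5-fold in MCF7 are given as single values, and no theme was tested. The adhesion gene CEACAM5 read 2960 in the array labelled CCL2 overexpression against 1816, a log2 ratio of 0.70 with an SD of 0.34 over 2 probe sets, and CEACAM6 read 5476 against 3493. MSMB, a secreted protein of the prostate and other glands, had 0.72 with an SD of 0.10 over 2 probe sets, and the gel-forming mucin gene MUC5B 0.69. The WNT feedback gene AXIN2 had 0.79 with an SD of 0.51, and the growth factor genes TGFA and TGFB3 had 0.68 each. Lower were the drug efflux gene ABCG2, with 322 against 577 and a ratio of -0.84, the calcification inhibitor gene MGP with -0.81 and AMIGO2 with -0.80.

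In MB231, PTGES, the synthase of prostaglandin E, read 1128 against 727 in the array labelled CCL2 shRNA, a log2 ratio of 0.63 with an SD of 0.20 over 2 probe sets. The cytokine gene IL11 read 4733 against 6733, a ratio of -0.51 with an SD of 0.13 over 2 probe sets. The laminin gene LAMA1 had -0.60 and the tau gene MAPT -0.60, with 2 of its 3 probe sets going that way. The control transcripts GAPDH and ACTB had log2 ratios of 3' over 5' signal of 0.17 to 0.25 and 0.31 to 0.64 over the 4 arrays. In the MB231 pair, ACTB had 0.31 in the non-silencing array and 0.41 in the array labelled CCL2 shRNA, while GAPDH had 0.17 in each. Whether this bears on the MB231 list medians was not tested.

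MALAT1, a long noncoding nuclear RNA, had 12 probe sets above the floor, and in MCF7 they went opposite ways. Probe sets 224559_at and 228582_x_at had log2 ratios of 1.51 and 0.87 and 226675_s_at -0.97, and in all 2 were above 0 and 10 below, while in MB231 224559_at had -0.93 and 228582_x_at -1.0001. The 3' over 5' ratios of GAPDH and ACTB differed by at most 0.032 between the MCF7 arrays, which argues against a difference in the integrity of those transcripts. They do not measure MALAT1, so a difference in the integrity of that RNA stays open. Noise of single probe sets stays open, since MALAT1 was picked for this spread and its range in MCF7, 15.9 technical SDs over the 12 probe sets, only describes it. A change in the processing or in the isoforms of MALAT1 may be a candidate explanation, and no test of it was made here.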
